A study of Mus musculus with 14 samples.

How the data were processed

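RNA-seq was carried out on individual mouse embryos at embryonic day 3.5, the blastocyst stage, from a Znhit1 line and a Znhit2 line. Per the labels' protocols, RNA was extracted from each embryo separately, and libraries were made with a NEBNext low-input kit and sequenced paired-end on an Illumina NextSeq. Groups were taken from the genotype given in the labels as wild type (WT), heterozygous (HET) and mutant (MUT). Each of the 14 libraries was a separate embryo, so the p-values of single genes below measure the spread between embryos. Fisher's exact and hypergeometric p-values take genes as units, and camera at the preset correlation compares genes, so these do not measure that spread. Parents, litter and processing day are not given in the sources used here.

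Per the submitters' processing notes, the authors used Trimmomatic 0.39, FastQC 0.11.9, STAR 2.7.6a, R 4.2.1 and DESeq2 1.36.0 with genome build GRCm39. The counting tool, the strand setting and the gene annotation are not given in the sources used here, so reads of overlapping or antisense genes could not be told apart. The deposited count sheets held whole-number counts per feature and embryo, not normalized. The count sheet of the Znhit2 line had 42552 features and 17.9 to 31.8 M counts (M, 1e6) per embryo. The count sheet of the Znhit1 line had 4096 genes and 8.17 to 10.4 M counts per embryo, and how those genes were chosen is not given in the sources used here.

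The deposited sheets named log2 RPKM held 814 features for Znhit1 and 2037 for Znhit2. In both, every value of a feature with a count was the log2 of its count per 1e6 of a single total per library, within 0.001, with no term for gene length, and a count of 0 was entered as 0.9 count. These sheets therefore gave each library's total as the authors used it. The totals were 31.0 to 38.7 M in the Znhit1 line, of which the count sheet held 26.3 to 27.4%. The authors' deposited tables of changed genes gave a log2 fold change and a p-value for 814 genes in the Znhit1 line and 1012 in the Znhit2 line. Per the file headers, neither the groups compared nor any correction of the p-values was named there.

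In the Znhit2 sheet 12101 features were named by a transcript accession. Of these, 10952 were matched to a gene symbol through RefSeq names and 1 through GENCODE names for build GRCm38, used for names only, and 1148 features holding 3.36% of the counts stayed unmatched. Coordinates are those in the deposited files. Of the 4096 genes of the Znhit1 sheet, 3835 were found by symbol in the Znhit2 sheet. All pairs of libraries within a line differed by far more than sampling noise, with a chi-square per degree of freedom of 169.2 to 559.5 over the 15 pairs of the Znhit1 line and 113.5 to 215.7 over the 28 pairs of the Znhit2 line. No library therefore looked like a second sequencing of another. The comparison is with read sampling alone, so it cannot tell separate libraries of the same embryo apart from libraries of different embryos. That each library was a separate embryo rests on the labels.

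Counts were tested with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood F-test after filterByExpr, with all 3 genotypes of a line in the fit and no covariates. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. The tests, samples, gene lists and rule for named genes were fixed before the data were examined. TMM factors had been planned for both lines and were used for Znhit2. For Znhit1, whose sheet held only part of each library and was rich in genes that differed, libraries were scaled to the deposited totals instead. This was chosen after seeing the data, and the TMM result is given beside it. CPM values, counts per 1e6 of the library, use the same library sizes, and errors on CPM are standard deviations (SD). Errors on log2 fold changes are standard errors (SE).

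A fold against a group whose libraries were all at 0 was computed against a floor of 3 counts over the group and is given as "at least". With 1 to 3 counts in the lower group, the ratio is given with its 95% exact Poisson counting interval. Intervals and floors cover counting error only, since reads made by PCR without molecular identifiers are not independent molecules. Fitted log2 values of genes with a group at or near 0 depend on edgeR's prior count.

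The 27 gene lists covered epiblast and pluripotency, primitive endoderm, trophectoderm, maternal and oocyte, 2-cell stage, p53 targets, integrated stress response, unfolded protein response and heat shock, apoptosis and lysosome, G1/S and DNA replication, G2/M and mitosis, ribosomal proteins, ribosome biogenesis and snoRNP, spliceosome, R2TP and ZNHIT2 partners, SRCAP with TIP60 and H2A.Z, cholesterol synthesis, glycolysis and hypoxia, nuclear oxidative phosphorylation, mitochondrially encoded genes, proteasome, histones, imprinted genes, germline genes silenced by DNA methylation, maternal blood cells, maternal oviduct with uterus and cumulus, and sex-linked markers. Members were matched by symbol, or by an older symbol that belonged to a single gene and was no other gene's current symbol. The conditions on older symbols were added after list results had been seen, when members were found matched to the wrong gene. Lists with at least 3 tested members were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01 for both directions, and again with an estimated correlation and with fry. The list tests of MUT against HET were not in the fixed plan. Camera compares a list with the other genes tested, which for Znhit1 are the preselected genes of its sheet. Fry asks instead whether a list differs from no change. In the Znhit1 sheet 36.3% of genes had an unadjusted edgeR p below 0.05. Rpl38 had an unadjusted edgeR p of 0.484 and an adjusted p of 0.487, so almost all genes of the sheet lay at or below 0.487. Genes with a large p for MUT against WT were thus few, and list members in that sheet do not stand for whole lists.

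Named genes followed a fixed rule. It took Znhit1 and Znhit2, the 10 largest rises and the 10 largest falls past the threshold with both mutants outside the range of the WT embryos and a mean log2(CPM + 1) of at least 2, and up to 4 members with the smallest p in each list described. Where fewer than 3 genes passed, it took the 5 with the smallest unadjusted p in each direction, or up to 5 for the comparisons with HET. It also took up to 10 genes moved in both lines and the 5 in each direction for the difference between lines. From the authors' tables it took the 3 largest folds in each direction. Unnamed gene models were left out.

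The single Znhit1 HET embryo was compared with the WT mean on log2(CPM + 1) without a test, and list medians were placed among 10000 random lists matched on mean expression. The mean of the logs was used for WT after the log of the mean had first been tried. The difference of the mutant effects between lines was tested as an interaction in a single edgeR fit over the genes in both sheets.

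The scripts were tested on simulated counts in which 200 genes were changed per line. A simulated list of 30 further genes was raised by 1 on the log2 scale in MUT. The counts were drawn with dispersions estimated by edgeR. For Znhit1 MUT against WT, over 3908 genes, edgeR called 13.4% of 2-fold, 43.3% of 4-fold and 49.2% of 16-fold changes, and 15 unchanged genes. For Znhit2 MUT against WT, over 14487 genes, it called 1.5%, 25.8% and 47% of those folds, and 1 unchanged gene. For the difference between lines, over 2962 genes, it called 5.4%, 25.9% and 46.2%, and 1 other gene, where the others included the raised list genes. On the same counts DESeq2 called 73 unchanged and 90 changed genes for Znhit1, and 166 unchanged and 98 changed genes for Znhit2, with the raised list genes among the changed.

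Alternatives were other scalings (DESeq2 size factors, TMM, quantile), other filters (none, or 5 CPM in at least 2 libraries), robust dispersions, the newer edgeR deviances, DESeq2 1.42.0, limma with library weights, the deposited log2 values, only the groups compared, WT and HET together as control, a term for Y-linked expression (Y-linked genes above 2 CPM in sum or not), removal of sex-linked genes, and each embryo left out in turn. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.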

Results

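The data were read counts per gene from 14 single mouse embryos at embryonic day 3.5. The Znhit1 line had 3 WT, 1 HET and 2 MUT embryos, and the Znhit2 line had 3 WT, 3 HET and 2 MUT embryos, with separate WT embryos in each line. ZNHIT1 is a subunit of the SRCAP chromatin remodelling complex, which deposits the histone variant H2A.Z. ZNHIT2 binds the RUVBL ATPases and takes part in the assembly of the U5 small nuclear ribonucleoprotein of the spliceosome. The series asks which transcripts differ when either gene is lost around implantation. Between 14228 and 16274 features were above 0 per embryo of the Znhit2 line, and between 2744 and 3275 of the listed genes in the Znhit1 line, whose sheet held only part of the transcriptome.

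Both targeted genes followed the genotype labels. Znhit1 (chromosome 5, 137011048 to 137016813, build GRCm39) stood at 77.3 ± 13.4 CPM (SD, n = 3) in WT embryos of its line, with counts of 2735, 2881 and 2402. The HET embryo had 1678 counts, and the MUT embryos had 1 and 0. The MUT level was 4956-fold lower than WT (95% counting interval 889.2 to 195800), with an adjusted p of 0.000155 by edgeR. Znhit2 (chromosome 19, 6111237 to 6112498) had 270, 317 and 665 counts in WT embryos of its line, 372, 249 and 180 in HET embryos, and 0 in both MUT embryos. Its MUT level was at least 347.6-fold lower than WT and at least 169.5-fold lower than HET, although its edgeR adjusted p against WT was 0.116. Znhit1 itself stood at 47.7 ± 5.72 CPM (SD, n = 3) in WT and 52.4 ± 9.33 CPM (SD, n = 2) in MUT embryos of the Znhit2 line, a log2 difference of 0.14 ± 0.26 (SE; an unadjusted edgeR p of 0.619).

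**Figure D1:**
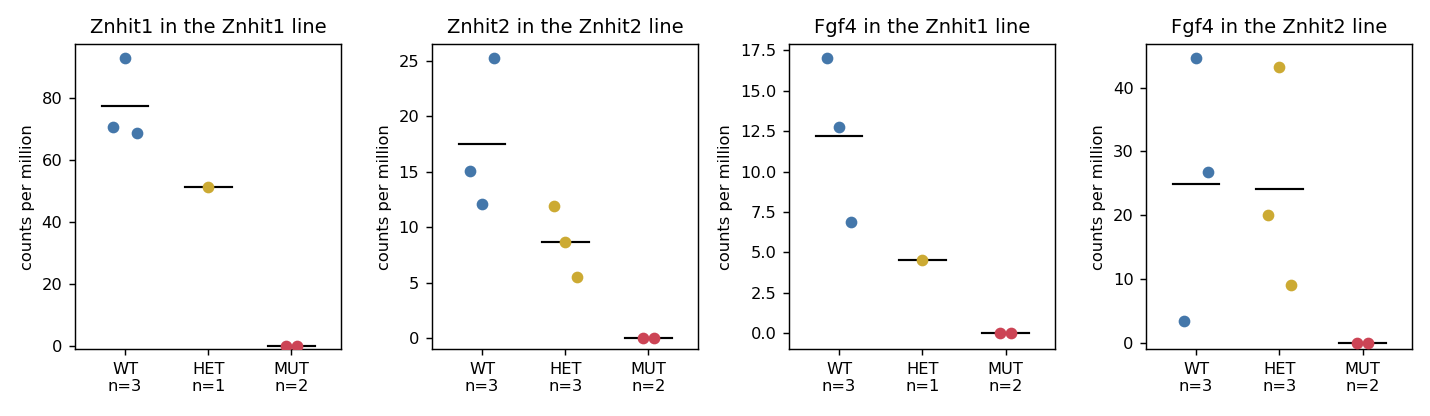
CPM of Znhit1 in the Znhit1 line, of Znhit2 in the Znhit2 line and of Fgf4 in both lines, by genotype, with a dot per embryo and a black line at the group mean. All MUT embryos lie at or close to 0 in each panel, and the Fgf4 panels show a wide spread among the WT embryos.

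Loss of Znhit1 was addressed by comparing MUT with WT embryos of that line. Adjusted p-values for this line cover only the genes of its sheet, which held few genes with a large p for this comparison. Counting genes outside the sheet with a p of 1 left 14 genes past the threshold. Fgf4, the growth factor that epiblast cells send to their neighbours, had 660, 396 and 242 counts in WT and 0 in both MUT embryos, at least 267.4-fold lower (adjusted p = 0.0394). Ccng1, the p53 target that encodes cyclin G1, rose from 86.7 to 290.1 CPM, a log2 change of 1.74 ± 0.34 (SE; adjusted p = 0.0346). Prim1, the DNA primase subunit, fell by 1.79 ± 0.27 (SE) on the log2 scale from 117 to 33.7 CPM (adjusted p = 0.0148). Mcm6, part of the replicative helicase, fell by 0.76 ± 0.17 (SE; adjusted p = 0.0415).

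The largest falls by fitted log2 value were in genes with 0 counts in both MUT embryos. Those values depend on edgeR's prior count, and the bounds below give no order of size. The MUT libraries had the fewest listed genes above 0, at 2744 and 2828 against 2992 to 3275 in the WT and HET libraries, not compared at a common depth. MUT replicate 7 had the highest shares of mitochondrial counts, at 3.93%, and of the 10 most abundant genes, at 16.8%. Gdi1, a regulator of Rab GTPases (chromosome X, 73348618 to 73355473), had 1613, 1089 and 2776 counts in WT embryos and was at least 1129-fold lower (adjusted p = 0.000979). Bnip1, an endoplasmic reticulum SNARE, was at least 603.1-fold lower, the RNA helicase Mov10 at least 592.1-fold and the cross-link repair nuclease Dclre1a at least 570.1-fold. The ubiquitin ligase Pja1, the ciliary protein gene Rpgr, the cytochrome P450 gene Cyp4f13 and the anion exchanger Slc4a2 were at least 463.4-, 423.4-, 413.7- and 407.3-fold lower. The zinc-finger genes Zfp446 and Zfp688 were at least 398.5- and 368.4-fold lower.

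Among genes that rose, 4 had 0 counts in all WT embryos. The double homeobox gene Duxbl1 (chromosome 14, 25979011 to 25990590) was at least 783-fold higher in MUT, the cyclin gene Ccnj at least 590.5-fold, Zc2hc1a at least 460-fold and Tmem170b at least 423.3-fold. The single HET embryo also had counts of all 4, with 547 for Duxbl1. The ubiquitin ligase Hectd3, the calcium-binding protein gene Calb2 and the oxidase Duox1 had ratios of 2174 (389.6 to 85950), 1150 (205.8 to 45500) and 952.1 (263 to 7871). Kctd3, Smg5, a factor of nonsense-mediated decay, and Trim43b rose by log2 values of 4.19 ± 0.92, 2.71 ± 0.61 and 2.04 ± 0.40 (SE). Duxbl1 and Trim43b have near-identical copies in the genome, so their counts are uncertain.

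In all, 161 genes of the Znhit1 sheet passed an adjusted p of 0.05 in edgeR, of which 25 rose and 136 fell, and 1485 had an unadjusted p below 0.05. MUT embryos were at 0 for 36 of the 136, and the median log2 change was −3.05 for genes that fell and 1.74 for genes that rose, with such genes at their bound. The split depended on the scaling: TMM over the sheet gave 204 genes (101 higher, 103 lower) and DESeq2 size factors 615 (453 higher, 162 lower), since the median log2 fold change of all genes was −1.25 with the deposited totals, −0.99 with TMM, −0.87 with size factors and −0.52 with quantile scaling. DESeq2 called 1932 genes, the newer edgeR deviances 6, a term for Y-linked expression left 21, counting genes outside the sheet with a p of 1 left 14, and limma with library weights or quantile scaling called 0, with 1274 and 1219 genes at an unadjusted p below 0.05. Without WT replicate 1, 2 or 3 the number was 18, 44 or 239. Without HET replicate 6, MUT replicate 7 or MUT replicate 9 it was 67, 2 or 1. In this line only WT replicate 1 and the single HET embryo had Y-linked expression. The Y-linked term thus rests on WT replicate 1 against the other WT embryos. Its effect cannot be told apart from leaving out that embryo.

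Of 39 p53 targets, 9 were in the Znhit1 sheet, and 8 of these were higher in MUT, 6 with an unadjusted p below 0.05. The sheet held few genes with a large p for this comparison. List members found in it therefore do not stand for the whole list, here and for the lists below. Ccng1 rose over all genes, and 3 rose adjusted over the list alone. The list passed camera upward (adjusted p = 0.00152) with a median log2 fold change of 1.74, but not with an estimated correlation (adjusted p = 0.582) or with fry (adjusted p = 0.0699). Cgref1, Perp and Rps27l had log2 values of 2.05 ± 0.51, 0.94 ± 0.27 and 0.50 ± 0.19 (SE).

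All 26 ribosomal protein genes in the sheet, of 77 listed, were higher in MUT, 7 with an unadjusted p below 0.05, and 0 passed edgeR over all genes or adjusted over the list alone. The sheet held few genes with a large p for this comparison, so the 26 do not stand for all 77. The list passed camera upward (adjusted p = 4.76e-05, or 0.666 with an estimated correlation) at a median of 0.30, with Rpl5, Rpl26 and Rps25 at 0.43, 0.44 and 0.40. Ribosome biogenesis also passed camera upward (adjusted p = 0.04; adjusted p = 0.582 with an estimated correlation), with 10 of 13 genes higher. None of them passed over all genes, while 5 rose and 1 fell adjusted over the list alone, with Nop58, a core box C/D snoRNP protein, at 0.65 and the nucleolar proteins Npm1 and Gnl3 at 0.45 and 0.78. These medians and that of the p53 list kept their sign under the totals, TMM, size factors and quantile scaling.

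All 8 epiblast genes in the sheet were lower in MUT, 7 with an unadjusted p below 0.05. Only Fgf4 fell over all genes and 5 fell adjusted over the list alone, and the list did not pass camera (adjusted p = 0.065). Sall4, Nr5a2 and Utf1, all expressed in pluripotent cells, had log2 values of −0.68, −0.96 and −1.20. Of 16 G1/S and DNA replication genes 12 were lower, Prim1 and Mcm6 fell over all genes, and 10 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.109). All 8 glycolysis and hypoxia genes were lower, with 0 past the threshold over all genes in edgeR, 6 at an unadjusted p below 0.05 and the same number falling adjusted over the list alone (camera adjusted p = 0.0704). Pgk1, Gpi1, Pkm and Aldoa of that list had log2 values of −1.38, −1.18, −0.76 and −0.52. The medians of the epiblast, G1/S and glycolysis lists were −1.17, −0.97 and −1.20, close to the median of all genes in the sheet, and kept their sign under each scaling.

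The remaining lists did not pass camera. The genes of the SRCAP, TIP60 and H2A.Z list in the sheet, Dmap1 at −0.88, Ing3 at −1.86 and Mrgbp, which was at 0 in MUT, were lower (adjusted p = 0.109), as was the condensin gene Ncapd2, which fell by 2.09, among G2/M genes (adjusted p = 0.337). The complex I gene Ndufs2 fell by 1.25 among 16 oxidative phosphorylation genes (adjusted p = 0.283), the meiotic cohesin gene Stag3 fell to 0 counts in MUT among 10 germline genes (adjusted p = 0.736), and Pdrg1 rose by a log2 value of 1.17 among 4 R2TP genes (adjusted p = 0.875). Adjusted p was 0.109 for 2-cell genes, 0.283 for histones, 0.292 for cholesterol synthesis, 0.337 for the proteasome, 0.381 for blood cells, 0.43 for primitive endoderm and for apoptosis, 0.451 for maternal genes and 0.565 for imprinted genes and the spliceosome. It was 0.632 for sex-linked markers, 0.736 for oviduct and for the unfolded protein response, 0.875 for trophectoderm and 0.892 for the integrated stress response. No member of the mitochondrially encoded list was found in the sheet by symbol, so the list was not tested. Mitochondrial features were nonetheless in the sheet, with 2.67 to 3.93% of its counts. The median and the camera direction differed in sign for the germline and apoptosis lists, and the median and the mean for the spliceosome. The medians of the stress response, apoptosis and germline lists changed sign with the scaling.

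Some macrophage-type transcripts were highest in WT replicate 2, with counts of 932 for Lyz2 against 0 and 0 in the other WT embryos, 8077 for Cd74 against 231 and 3813, and 274 for C1qc against 0 and 0. The HET embryo had 151 counts of Lyz2 and 883 of Cd74, and Fcer1g went the other way, with 93 counts in WT replicate 2 against 125 and 166 in the other WT embryos and 251 in the HET embryo. All 7 blood-cell genes of the list were lower in MUT, but Gypa, C1qb, C1qc and Tyrobp had counts in WT replicate 2 only. Y-linked genes summed to above 2 CPM in WT replicate 1 and the HET embryo of this line, at 196.6 and 113.5 CPM, and to at most 0.114 CPM in the other embryos.

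The single Znhit1 HET embryo was compared with WT to see whether a reduced dose moves the genes that changed in MUT. Its Znhit1 level was 51.3 CPM, 66.4% of WT. Of the 25 genes that rose in MUT it lay above all WT embryos for 17, and of the 136 that fell it lay below all WT embryos for 63. These genes were chosen by their difference from the same 3 WT embryos, so the numbers have no chance value to set them against and are no test of dose. Their median log2 differences from WT were 0.77 and −0.34. The p53 list had a median of 0.55, at percentile 98 of random matched lists, but a mean of 0.27, within the range of the WT embryos, the highest of which was at 0.32. Among other lists, the epiblast list had a median of −0.74 at percentile 0.5, and the G1/S list of −0.50 at percentile 0.1. Oxidative phosphorylation genes (14 of 16 lower, percentile 1.8), primitive endoderm genes (6 of 6 lower, percentile 2.5) and ribosome biogenesis genes (median 0.21, percentile 94.4) also had the direction seen in MUT. Some lists did not: ribosomal proteins, all higher in MUT, had a median of −0.06 with 17 of 26 lower, glycolysis genes, all lower in MUT, −0.03 at percentile 48.9, and the 3 genes of the SRCAP, TIP60 and H2A.Z list, all lower in MUT, were all higher at 0.41. Over all genes the median difference was −0.08, or −0.041 with TMM. It was −0.02, −0.018 or −0.051 without WT replicate 1, 2 or 3, and with 1 embryo there is no replicate check.

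**Figure D2:**
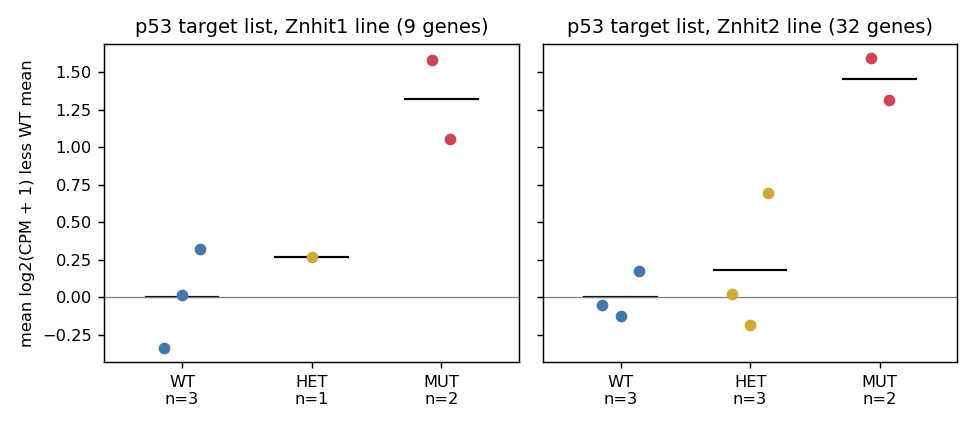
Mean over the p53 target list of log2(CPM + 1) less the WT mean, by genotype, with a dot per embryo and a black line at the group mean, for 9 genes in the Znhit1 line and 32 in the Znhit2 line. The MUT embryos lie at 1.58 and 1.05 in the Znhit1 line and at 1.59 and 1.31 in the Znhit2 line, above every WT and HET embryo, the highest of which is a Znhit2 HET embryo at 0.695.

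Loss of Znhit2 was addressed in the same way in its own line. No single gene passed in edgeR, and the p53, spliceosome and ribosome biogenesis lists (higher in MUT) and the replication list (lower) passed camera only at the preset correlation. With an estimated correlation none of them passed (adjusted p = 0.122 with an estimated correlation for the first 3 and 0.38 for replication). Fry, which sets a list against no change, gave an adjusted p of 0.0302, 0.0193 and 0.0223 for the first 3. For replication fry gave an adjusted p of 0.154. Sesn2, a p53-inducible stress protein (chromosome 4, 132220115 to 132237767), stood at 33.2 ± 5.91 CPM (SD, n = 3) in WT, 71.3 ± 17.5 in HET and 219.7 ± 0.845 (SD, n = 2) in MUT, a log2 difference of 2.73 ± 0.26 (SE; adjusted p = 0.0576 by edgeR). Wdr61, a subunit of the PAF1 and SKI complexes (chromosome 9, 54624437 to 54641833), stood at 210.0 ± 6.53 CPM in WT, 163 ± 10.9 in HET and 73.3 ± 3.74 in MUT, a difference of −1.52 ± 0.14 (SE; adjusted p = 0.0576 by edgeR). Fgf4 had 63, 1172 and 704 counts in WT, 625, 1237 and 298 in HET, and 1 and 0 in MUT embryos, a ratio of 1615 (289.5 to 63830) with an unadjusted edgeR p of 0.000775.

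The genes with the smallest p, none of which passed, had levels that did not overlap between MUT and WT embryos. The membrane protease St14 (chromosome 9, 30999886 to 31043138) had a log2 difference of 1.90 ± 0.18, the guanine nucleotide enzyme Impdh1 of 1.33 ± 0.18, the histone H3 lysine methyltransferase Setd2 of 1.43 ± 0.20 and the ubiquitin ligase Arih2 of 1.14 ± 0.16 (SE). Lower in MUT were the cytoskeletal GTPase Septin7 at −0.84 ± 0.10, the heat shock factor Hsf1 at −2.19 ± 0.27 (72.9 to 15.9 CPM) and Rogdi at −2.52 ± 0.32 (214 to 37.2 CPM). For St14 and Impdh1 the HET embryos, at 112 and 113 CPM, lay near the MUT embryos, at 125 and 132 CPM, and not near WT, at 33.6 and 52.4 CPM.

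**Figure D3:**
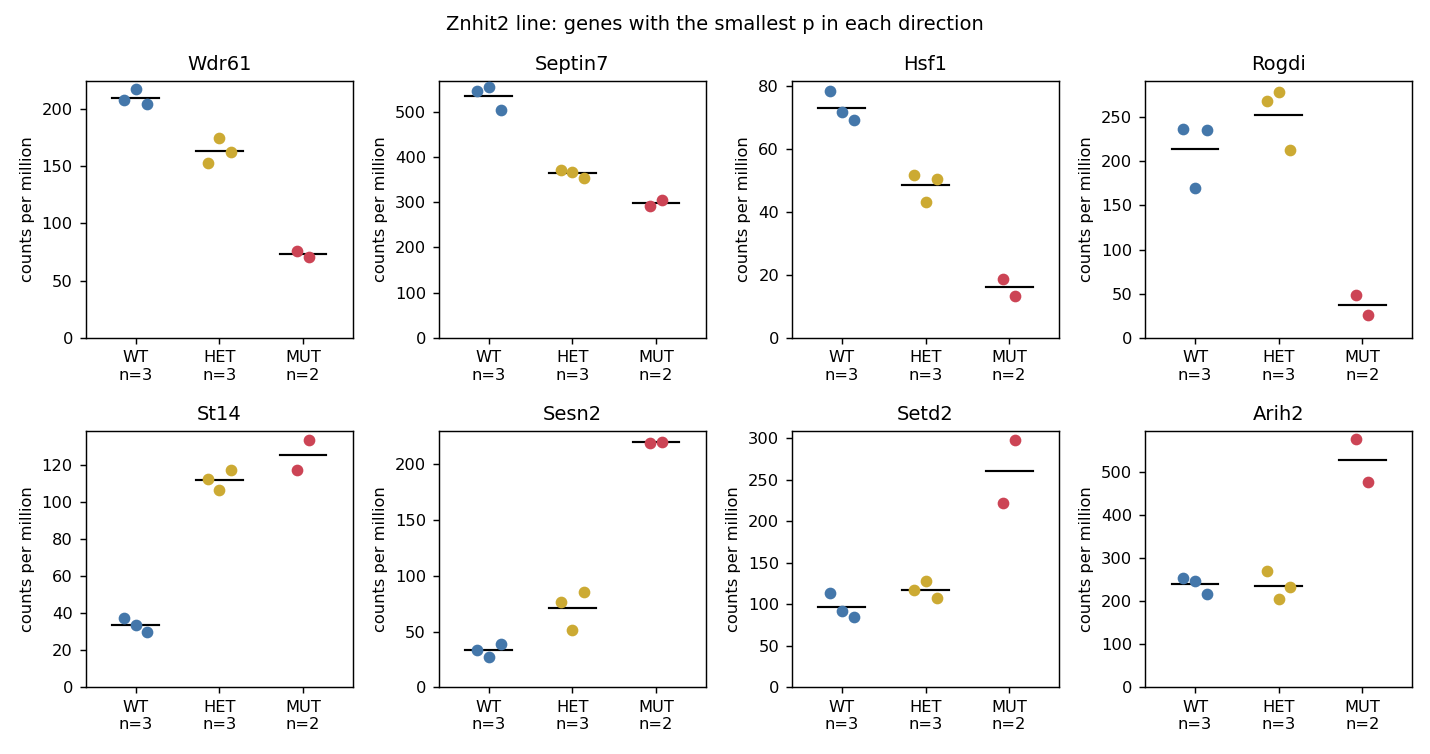
CPM of Wdr61, Septin7, Hsf1, Rogdi, St14, Sesn2, Setd2 and Arih2 in the Znhit2 line by genotype, with a dot per embryo and a black line at the group mean. The MUT embryos lie outside the range of the WT embryos in every panel, and for St14 the HET embryos lie at 112 CPM, near the MUT mean of 125 CPM.

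edgeR called 0 of 15184 genes at an adjusted p of 0.05, with 1524 genes at an unadjusted p below 0.05 (690 higher, 834 lower). DESeq2 called 714 (238 higher, 476 lower), the newer edgeR deviances 2, and limma with library weights or quantile scaling 0, while limma on the features with deposited log2 values called 763. On simulated counts of this design, drawn with dispersions estimated by edgeR, edgeR called 25.8% of 4-fold and 1.5% of 2-fold changes, and DESeq2 also called 166 of 14259 unchanged genes.

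Of 32 p53 targets, 29 were higher in MUT and 13 had an unadjusted p below 0.05, with 0 past the threshold over all genes in edgeR and 11 that rose adjusted over the list alone. The list passed camera upward (adjusted p = 1.43e-13; adjusted p = 0.122 with an estimated correlation) at a median of 1.05, and fry gave an adjusted p of 0.0302. After Sesn2, the smallest p belonged to Gtse1, Psrc1 and Ddit4l at log2 values of 1.60 ± 0.24, 1.56 ± 0.31 and 1.90 ± 0.43 (SE). The canonical targets Mdm2 and Cdkn1a, named here after their values were seen, had log2 values of 1.16 ± 0.30 and 1.97 ± 0.52 (SE).

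Of 57 spliceosome genes 48 were higher in MUT, 15 with an unadjusted p below 0.05, with 0 in edgeR over all genes or adjusted over the list alone. The list passed camera upward (adjusted p = 3.35e-07; adjusted p = 0.122 with an estimated correlation) at a median of 0.31. Snrpb, a core Sm protein, Sf3b1, of the U2 particle, the splicing factor Srsf7 and the helicase Dhx15 had log2 values of 0.51, 0.76, 0.37 and 0.63. Of 49 ribosome biogenesis genes 31 were higher, 7 with an unadjusted p below 0.05 and 0 in edgeR over all genes or adjusted over the list alone (camera adjusted p = 0.0165; adjusted p = 0.122 with an estimated correlation; median 0.17). Pes1, Utp18, Mphosph10 and Polr1a of that list had values of 0.67, 0.57, 0.86 and 0.98.

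Of 42 G1/S and DNA replication genes 34 were lower in MUT, 10 with an unadjusted p below 0.05 and 0 in edgeR over all genes or adjusted over the list alone. The list passed camera downward (adjusted p = 3.35e-07; adjusted p = 0.38 with an estimated correlation) at a median of −0.45. The polymerase alpha subunit Pola2, Uhrf1, the partner of the maintenance DNA methyltransferase, the replication factor Cdc45 and the clamp loader subunit Rfc5 had log2 values of −1.53, −1.38, −1.28 and −0.94. The medians of these 4 lists kept their sign under TMM, size factors and quantile scaling.

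The other lists did not pass camera in this comparison. Adjusted p was 0.0534 for oviduct genes, 0.142 for epiblast, 0.183 for cholesterol synthesis, oxidative phosphorylation and ribosomal proteins, 0.287 for germline, 0.304 for the SRCAP, TIP60 and H2A.Z list, 0.361 for imprinted genes and 0.476 for trophectoderm and R2TP genes. It was 0.48 for 2-cell genes, 0.494 for glycolysis, whose median changed sign with quantile scaling, 0.734 for the proteasome and 0.759 for primitive endoderm and the unfolded protein response. For integrated stress response, apoptosis, G2/M, histone, maternal and sex-linked genes it was 0.781, and blood-cell and mitochondrially encoded lists had only 2 tested members. Of the 15 listed mitochondrially encoded genes only 2 were found by symbol, although mitochondrial features held 1.35 to 1.98% of the counts. The median and the camera direction differed in sign for the 2-cell, maternal, stress response and apoptosis lists, and the maternal, stress response and apoptosis medians changed sign with quantile scaling. The median and the mean differed in sign for the primitive endoderm, unfolded protein response, G2/M, R2TP, glycolysis, maternal and apoptosis lists.

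The comparison of Znhit2 HET with WT embryos asked what follows the loss of a single copy. Znhit2 itself stood at 8.71 ± 3.21 CPM (SD, n = 3) in HET against 17.5 ± 6.91 in WT. St14 had a log2 difference of 1.73 ± 0.16, the growth factor receptor Fgfr1 of 1.32 ± 0.19, Impdh1 of 1.11 ± 0.16 and the heterochromatin co-repressor Trim28 of 0.89 ± 0.14 (SE), while Septin7 was at −0.56 ± 0.09 and Piwil2, of the germline small RNA pathway, at −2.10 ± 0.38. Nt5e was higher with a ratio of 200.4 (68.34 to 974), Akap11 was lower with a ratio of 388.4 (107 to 3214), the DNA repair gene Mgmt was at least 191.6-fold lower, and Zfp14 was at −5.83 ± 1.08.

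None of these genes passed: edgeR called 0 genes (smallest adjusted p = 0.154), 944 had an unadjusted p below 0.05, DESeq2 called 143 (84 higher, 59 lower) and limma with library weights or quantile scaling 0. Camera passed 6 lists, of which 0 held with an estimated correlation. Ribosomal proteins were lower in 71 of 77 (adjusted p = 8.19e-08; adjusted p = 0.855 with an estimated correlation; median −0.14) and proteasome genes in 28 of 32 (adjusted p = 0.00121; adjusted p = 0.166 with an estimated correlation), with Psmd13, of the proteasome lid, at −0.47. Germline genes (adjusted p = 0.00262), oxidative phosphorylation (0.0274) and G1/S genes (0.0317) were lower and cholesterol synthesis genes (0.0274) higher, all with an adjusted p of 0.855 with an estimated correlation. No member of the 6 lists passed in edgeR over all genes, 1 germline and 1 proteasome gene fell adjusted over the list alone, and 9, 3, 3, 2, 2 and 0 members of the ribosomal, proteasome, germline, oxidative, G1/S and cholesterol lists were lower at an unadjusted p below 0.05, against 0, 0, 1, 1, 1 and 1 higher. The oxidative phosphorylation median of −0.08 came to 0 with quantile scaling, and the other 5 kept their sign.

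The comparison of Znhit2 MUT with HET embryos asked what follows the loss of the remaining copy. The p53 list passed camera upward at the preset correlation but not with an estimated one (adjusted p = 0.0943 with an estimated correlation), and fry gave an adjusted p of 0.0296. Fgfr1 had the smallest p, with 3784, 3029 and 3871 counts in HET and 499 and 620 in MUT embryos, a log2 difference of −2.60 ± 0.23 (SE; adjusted p = 0.107 by edgeR). Rogdi, Wdr61 and the tight junction gene Marveld2 were at −2.76 ± 0.32, −1.15 ± 0.13 and −8.19 ± 1.03. Arih2, the nucleolar helicase Ddx21, the autophagy protein gene Gabarapl2, Gtse1 and Sesn2 were at 1.16 ± 0.16, 1.01 ± 0.15, 0.44 ± 0.07, 1.51 ± 0.24 and 1.62 ± 0.26 (SE). edgeR called 0 genes with 1415 at an unadjusted p below 0.05, DESeq2 called 644 (201 higher, 443 lower), and limma with library weights or quantile scaling 0.

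Camera passed 8 lists here, of which 0 held with an estimated correlation. The p53 list was higher (29 of 32; 8 rose and 1 fell adjusted over the list alone; adjusted p = 6.27e-12; adjusted p = 0.0943 with an estimated correlation; median 1.19). Ribosomal proteins were higher (72 of 77; adjusted p = 3.08e-09; adjusted p = 0.428 with an estimated correlation), as were spliceosome genes (47 of 57; adjusted p = 3.94e-07; adjusted p = 0.0823 with an estimated correlation) and ribosome biogenesis genes (33 of 49; 3 rose adjusted over the list alone; adjusted p = 0.00119; adjusted p = 0.0823 with an estimated correlation). Cholesterol synthesis genes were lower (22 of 23; adjusted p = 0.00044; adjusted p = 0.437 with an estimated correlation), with Pmvk and Fdps at −1.03 and −1.11. G1/S genes were lower (31 of 42; 3 fell adjusted over the list alone; adjusted p = 0.0016; adjusted p = 0.428 with an estimated correlation), with Pold1 at −1.91 and Uhrf1 at −1.74. Epiblast genes were lower (19 of 24; 1 rose and 1 fell adjusted over the list alone; adjusted p = 0.0193; adjusted p = 0.399 with an estimated correlation), and so were the oviduct genes Msx1, Wfdc2 and Muc1, which all fell adjusted over the list alone (adjusted p = 0.00594; adjusted p = 0.28 with an estimated correlation). In edgeR 0 members of these lists passed over all genes, and the medians kept their sign under each scaling.

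The 2 lines were set side by side because the series asks where their mutants overlap. Fgf4 was at or near 0 in all 4 MUT embryos and counted in all 10 other embryos. Ogfr, the opioid growth factor receptor, was at 0 in all 4 MUT embryos, at least 126.1-fold lower than WT in the Znhit1 line and at least 193-fold lower in the Znhit2 line. The kinase Tesk1, the carbonic anhydrase Car2 and Gstk1 were also at 0 in all MUT embryos, though each was at 0 in at least 1 WT or HET embryo as well, and Prpf40b and Hapln4 were lower in both lines, with log2 values of −4.41 and −2.59 in the Znhit2 line. D1Pas1, a testis copy of Ddx3x, was at 0 in WT of both lines and at least 271.3-fold and 334.6-fold higher in MUT, but 1 of the Znhit1 MUT embryos was at 0. Zfp9 had ratios of 746.6 (206.1 to 6174) and 204.1 (36.14 to 8108), and Pramel48 was higher by log2 values of 3.63 and 2.50. D1Pas1 and Pramel48 have near-identical copies, and among these genes only Fgf4 passed an adjusted p of 0.05, in the Znhit1 line.

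Of 2970 genes tested in both lines, 43 were higher in both mutants at an unadjusted p below 0.05, where independent lists give 18.9 (one-sided Fisher's exact p = 5.26e-08). In the same way 93 were lower in both, where independent lists give 61.9 (Fisher's exact p = 9.9e-07), and 35 went opposite ways, where they give 71.8. Both p-values take genes as independent units and do not measure the spread between embryos. At an adjusted p of 0.05 the overlap by edgeR was 0, against 136 at an unadjusted p, because Znhit2 had no such gene. Across these genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.101 and a Spearman rho of 0.103, and r was 0.241 over the 1480 genes above 20 counts in all 14 libraries. The lines share no control embryos.

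The mutant effect differed between the lines for 106 of 3835 genes (22 higher and 84 lower in the Znhit1 line; edgeR interaction, adjusted p below the threshold), with 903 at an unadjusted p below 0.05. These 3835 are genes of the Znhit1 sheet, which held few genes with a large p for its own MUT against WT. Such a set favours a difference between the lines, and the adjustment covers these genes only. The split of directions depended on the scaling, with 77 higher and 71 lower under DESeq2 size factors. The endosomal sorting nexin Snx5 was at −1.36 in the Znhit2 line and 0.29 in the Znhit1 line, a difference of 1.65 ± 0.26 (SE; adjusted p = 0.00132). The focal adhesion protein gene Zyx, Septin7 and the calmodulin gene Calm2 were also lower in Znhit2 mutants and not in Znhit1 mutants, with differences of 2.74 ± 0.48, 1.37 ± 0.25 and 0.94 ± 0.18, and Tmem170b had no counts in the Znhit1 WT embryos but counts in every embryo of the Znhit2 line. Znhit1, the sugar transporter Slc35b4, Cnpy2, the TFIID subunit Taf6 and the kinase Map2k7 were lower in the Znhit1 line with larger differences: Slc35b4 and Map2k7 were at 0 in its MUT embryos, at least 356.2-fold and 267.8-fold lower, and Cnpy2 had a ratio of 1547 (529 to 7502). Without Znhit1 MUT replicate 7, Znhit1 MUT replicate 9, Znhit2 WT replicate 1 or Znhit2 MUT replicate 8 the number was 45, 53, 67 or 63.

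The authors' deposited table for Znhit1 listed 182 genes as higher and 632 as lower, and that for Znhit2 listed 269 as higher and 743 as lower. The erythrocyte membrane gene Epb42 and Pfn4 and Ube2u had the largest rises in the authors' deposited table for Znhit1, at log2 values of 24.64, 24.48 and 24.46, and Eif2s3y, which is Y-linked, Ints6l and CN725425 the largest falls, at −25.41, −24.27 and −24.08. In the authors' deposited table for Znhit2 they were Aga, Map10 and Acot6 at 24.97, 24.45 and 23.95, and Gramd1a, Myl9 and Wfs1 at −23.74, −23.63 and −23.63. Znhit1 and Znhit2 stood at −12.10 and −11.12 in the authors' deposited table of their own line. All genes of the authors' deposited table for Znhit1 had the same direction in the edgeR fit here, 677 of them with an unadjusted p below 0.05, and 141 of the 161 genes called here were listed. Of the 879 listed Znhit2 genes tested here, 853 had the same direction against WT and 878 against WT and HET together. The authors' deposited tables shared 55 genes, 47 of them in the same direction. Within the 15184 genes tested here in the Znhit2 line, taken as the background of both tables, 12 rose in both, where independent lists give 2 (hypergeometric exact p = 9.84e-07). In the same background 31 fell in both, where independent lists give 24.4 (hypergeometric exact p = 0.101).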

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

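Of the tests in this part, those for fewer detected features, for DNA carried beside the target and for WT embryos that stand apart were chosen after the result was seen. The mutant effect differed between the Znhit1 and Znhit2 lines for 106 genes by the edgeR interaction test, which is a difference between groups. Only genes of the preselected Znhit1 sheet could be tested for this. As log2 differences, Znhit1 minus Znhit2, these were −12.09 for Znhit1, −12.12 for Slc35b4, −8.93 for Cnpy2, −8.37 for Taf6, −11.26 for Map2k7, −10.6 for Mov10, −13.34 for Dclre1a, −12.94 for Pja1, −10.65 for Rpgr and −11.2 for Slc4a2. Further values were −12.09 for Zfp688, −11.37 for Gdi1 and −12.2 for Zfp446, and on the other side 1.65 for Snx5, 2.74 for Zyx, 1.37 for Septin7, 0.94 for Calm2, 11.68 for Tmem170b, 1.51 for Rogdi and 11.19 for Hectd3. Values beyond 8 log2 come from genes with a group at or near 0, depend on edgeR's prior count and are no bounds. No group had 4 or more embryos, so no single embryo could be tested as standing apart.

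The genes at or near 0 in both Znhit2 MUT embryos and counted in every other embryo of the line were 14: Znhit2, Fgf4, Pomt1, Ogfr, Prom1, Stra8, Rnf225, Zfp59, Nudt7, Adad2, Fxyd6, Dusp1, Acsbg3 and a transcript without a symbol. Random loss of transcripts in low-input libraries stays open as an explanation, since another pair of the 28 had 22 such genes, although Znhit2 itself is the targeted gene. Fewer detected features in the mutants were argued against: at 1 depth the higher mutant had 15520 features against a median of 15080 in the 6 others. DNA of another strain carried beside the target was argued against as well, with 0 of these genes within 10 Mb of Znhit2 and 13 elsewhere. That test replaced, after its result was seen, a share of genes at an unadjusted p below 0.05 near Znhit2 of 12.3% against 9.99% elsewhere (Fisher's exact p = 0.141), which had left the question undecided.

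The p53 targets passed camera upward in the mutants of both lines at the preset correlation, but in neither line with an estimated correlation (adjusted p = 0.582 with an estimated correlation for Znhit1 and 0.122 for Znhit2), and fry gave an adjusted p of 0.0699 for Znhit1 and 0.0302 for Znhit2. The tests of the 2 lines are not alike. Of 39 targets 32 were tested in the Znhit2 line. Only 9 were tested in the Znhit1 line, from a sheet with few genes at a large p for MUT against WT. A factor common to all genes of a library was argued against in the Znhit2 line, since the list median lay 1.054 above that of all genes; TMM and size factors are not separate checks of this, as such factors cancel in the difference, and quantile scaling, which does not cancel, gave 1.541. For the Znhit2 line only, WT embryos that stand apart were argued against by a median of 1.19 against HET (1.186), and the sex of the embryos by a median of 1.35 with a term for Y-linked expression (1.346). In the Znhit1 line the same term cut the genes called from 161 to 21. The list median there kept its direction with the term, within 1.04 to 2.12 over the edgeR alternatives. In that line the term rests on WT replicate 1 against the other WT embryos. It therefore cannot weigh sex apart from that single embryo. Litter and processing day are not recorded and could not be tested. A p53 response to the loss of either gene is a possible explanation that these values leave open as a hypothesis only.

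The genes at or near 0 in all 3 Znhit2 WT embryos and counted in every HET and MUT embryo were 5: Ciz1, Gstm6, Zfp653, Gm51770 and Gm17586, chosen after their values were seen. Random loss of transcripts stays open here too, since other sets of 3 embryos had up to 10 such genes and several had at least as many. DNA carried beside the target was argued against, with 0 of them within 10 Mb of Znhit2 and 5 elsewhere. No biological explanation was tested for this pattern.

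For Znhit2 HET against WT, all 10 splits of the 6 embryos into 3 and 3 gave 0 genes in edgeR at the adjusted threshold, the real split included. The real split had 944 genes at an unadjusted p below 0.05 and the others 651 to 934, and 10 splits are too few for a share under 0.05.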

How the results depend on the processing

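The TMM scaling of Znhit1, the genes outside its sheet counted with a p of 1, the newer edgeR deviances, the pooled control in DESeq2 and the p53 medians under the edgeR alternatives were added after the data were seen. Of the values of named genes under the alternatives, 256 kept direction and side of the threshold and 197 became weaker in Znhit1 MUT against WT, where 1 of 21 genes stayed past it with either MUT embryo left out alone and 0 with limma weights or quantile scaling. In the Znhit2 comparisons, where no gene had passed, 572 stayed the same, 48 became stronger and 1 reversed: Znhit1 in Znhit2 MUT against WT was −0.058 without MUT replicate 8, in a range of −0.058 to 0.306. The p53 medians kept their direction in all 47 edgeR alternatives, at 1.04 to 2.12 for Znhit1 and, for Znhit2, 0.97 to 1.45 against WT and 0.93 to 1.47 against HET. DESeq2, limma and the pooled control were not among the 47. Quantile scaling, also outside them, gave medians of 1.824 for Znhit1 and, for Znhit2, 1.556 against WT and 1.315 against HET.

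For Znhit1 MUT against WT, 161 genes became 121 with a filter of 5 CPM, 204 with TMM, 173 with robust dispersions, 117 with WT and HET together as control, and stayed at 161 without a filter or without sex-linked genes. They became 615 with DESeq2 size factors, 21 with a term for Y-linked expression, 6 with the newer edgeR deviances, 67 with only the groups compared, 1932 with DESeq2, 1432 with DESeq2 and the pooled control, 614 with limma on the deposited log2 values, and 14 with genes outside the sheet counted. The 614 genes come from a test of only the features in the deposited log2 sheet. That sheet held as many features as the authors' deposited table of changed genes for this line. The 614 are therefore not a count over the same genes as the 161. Limma with library weights gave 0 and quantile scaling 0. The term for Y-linked expression amounts, in this line, to setting WT replicate 1 apart from the other WT embryos. Leaving out each WT or MUT embryo gave 1 to 239, where fewer embryos also mean less power. The cause was not tested for the others.

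For Znhit2 MUT against WT, 0 genes became 2 with the newer edgeR deviances, 714 with DESeq2, 852 with DESeq2 and the pooled control, and 763 with limma on the deposited log2 values. The 763 genes come from a test of only the features in the deposited log2 sheet of this line. They are therefore not a count over the same genes as the 0. DESeq2 gave 143 for HET against WT and 644 for MUT against HET, and the cause was not tested. All other alternatives and each embryo left out gave 0. The 106 genes whose effect differs between the lines became 148 with DESeq2 size factors and 45 to 155 with each embryo left out. The overlap of the lines was 136 genes at an unadjusted p.

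With an estimated correlation 0 gene lists passed in Znhit1 MUT against WT, 0 in Znhit2 MUT against WT, 0 in HET against WT and 0 in MUT against HET, and with fry 6, 3, 1 and 3. The 6 with fry in Znhit1 were the epiblast, G1/S, imprinted, primitive endoderm, proteasome and SRCAP lists, and none of the 3 that passed camera. The 2 tests ask different questions. Fry sets a list against no change, and camera sets it against the other genes tested, where the median of all genes was −1.25. The cause for each list was not tested. The median difference of the Znhit1 HET embryo, −0.079, became −0.041 with TMM, −0.072 with size factors and −0.051 to −0.018 with each WT embryo left out; the cause was not tested. Pseudocounts of 0.1 and 0.5 were not run because the values are counts. No paired analysis was possible because the groups compared within a line share no replicate numbers and no litter is recorded. At the depth of the Znhit2 line, a gene at 0 in both MUT embryos can only be given a bound.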

Other observations

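The position of genes was looked at after the named genes had been seen. Of 73 genes with an unadjusted edgeR p below 0.001 in Znhit2 MUT against WT, 11 lay on chromosome 9, which held 851 of the 15184 genes tested, where an even spread gives 4.09 (Fisher's exact p = 0.00236; 0.0495 after adjustment over 21 chromosomes). At an unadjusted p below 0.05 the share on chromosome 9 was 9.28% against 10.1% elsewhere. Wdr61 and St14 lie on this chromosome, and Znhit2 lies on chromosome 19.

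Akap11 and Cdkl4 were counted in all WT embryos of the Znhit2 line and at 1 count or 0 in every HET and MUT embryo, and are named after their values were seen. Akap11 had 115, 345 and 132 counts in WT, and Cdkl4 had 140, 119 and 153.

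Markers of other tissues differed between single embryos of the Znhit1 line. WT replicate 1 had 426 counts of Col1a1, 429 of Dcn and 279 of Vim, and WT replicate 2 had 109 of Tyrobp and 119 of C1qb, each the highest of the 6 embryos. Msx1 had 168 counts in the HET embryo and 194 and 165 in the MUT embryos, against 0, 3 and 0 in WT.

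Y-linked genes summed to 193.6 CPM or more in all 3 WT embryos of the Znhit2 line, in HET replicates 4 and 6 and in MUT replicate 9. They summed to 0.543 CPM in HET replicate 5 and 1.57 CPM in MUT replicate 8, below the 2 CPM taken as detected. In the authors' deposited tables, a fold beyond 10 log2 was given for 169 genes of the Znhit1 line and 152 of the Znhit2 line.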
